A study of Mus musculus with 6 samples.

How the data were processed

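Lavage cells were plated for a short time, washed and lysed on the plate, and total RNA was sequenced, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.18.0.12, STAR 2.5.2b, HTSeq 0.6.0 and DESeq2 were used, with the mouse genome build mm10. The roles of these tools, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. The deposited values are a normalized signal, which the tests below showed to be gene read counts divided by 1 size factor per library, and the table holds 22962 genes in 6 libraries. A symbol was found for 22873 of the gene identifiers, and positions were taken from an annotation of GRCm38, the assembly that mm10 names. Because the strand setting is not given, reads of genes that overlap on opposite strands could not be told apart, and the levels of overlapping genes and near-identical family members are uncertain.

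Each library's values were whole multiples of the value of 1 read. Dividing by it gave whole reads for 100% of the values above 0 in each library (within 0.05 of a read). Size factors recomputed from the recovered reads by the DESeq2 method equalled those implied by the deposited values. The recovered totals were 27654799 to 37147983 reads per library, so a gene at 3 reads had a value of 2.59 to 3.3 and changes of genes near that level rest on few reads. For genes at 0 in a group, folds are bounds against a floor of 3 reads over the group, and for genes with 1 to 3 reads a ratio with its 95% binomial counting interval is given. These cover counting error only.

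Samples were grouped by the treatment named in the labels. Genes with a value of at least 10 in at least 3 libraries were tested, 13512 in all, with limma 3.58.1 in R 4.3.3 on log2(value + 1). The moderated test used an intensity trend, was two-sided and compared the groups with no other term, and p-values were adjusted by the Benjamini-Hochberg method. A fold change on this scale understates the change of low genes. In all, 30 gene lists covering macrophage types, metabolism, injury responses and other cell types were fixed, and 27 with at least 3 tested members were set-tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. By camera 26 lists were called (21 higher, 5 lower), 3 with an estimated correlation, and fry called 20. The form with an estimated correlation also uses only the few residual degrees of freedom of the fit, which makes it stricter whatever the correlation. The lists, tests, filter, alternatives and rule for naming genes were chosen before the data were examined, apart from 2 alternatives, the tests of dilution and of neutrophils, and the gene families, which were added later.

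The rule named the 8 largest rises and 8 largest falls among called genes with a mean of at least 100 in the higher group, no overlap between groups and no predicted gene, the 3 members of each list with the smallest p (2 for markers of other cell types), and 12 genes whatever their result. Pfkp, Il18, Ptges, H2-Aa, H2-Ab1, H2-DMa, P4ha2, Ddit4, Ighm, Fcrla, Klrd1, Epcam, S100a8, S100a9, Lcn2, Col3a1, Lyz2, Tfeb, Ndufv1, Uqcrfs1, Mcm3, Mcm4, Mcm6, Top2a, Tpx2, Ccl2, Cxcl3, Mmp14 and Ctsk were named after their values were seen. Genes under the rule that did not help the account of a list are given only in its counts.

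Alternatives were pseudocounts of 0.5 and 5, no filter, a minimum of 50, TMM rescaling, quantile normalization, robust variances, no trend, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, a block on the replicate number, and leaving out each library. With the block the group difference rests on replicates 1 and 2 of each group alone, because numbers 3 and 5 each occur in 1 group. Leaving out saline replicate 2 and bleomycin replicate 1 together, and removing each library's trend with exon length, were added after the data were seen. Over the recovered reads edgeR called 1821 genes and DESeq2 2313. The fit was tested on simulated counts for 13512 genes, of which 13075 passed the filter, in the same 3 against 3 comparison. In it 200 genes were changed 2-fold or 4-fold, and 5 lists of other genes were shifted by a smaller amount. Simulated saline means were set to at least 10, so genes near 0 in saline were not covered. The 200 genes held as many rises as falls, whereas 13.7% of genes were called in the data, most of them rises. Recovery at that share, and any effect of the imbalance on the size factors, were therefore not covered either. There limma recovered 71.3% of 2-fold and 94.8% of 4-fold changes, with 6.67% of its calls on unchanged genes. Camera called 5 of 5 shifted lists and 0 of 15 others. The simulated genes were drawn independently, whereas estimated correlations within the real lists reached 0.876. The simulation therefore cannot show how often camera at the preset correlation calls unshifted lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.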

Results

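Gene expression was measured by RNA sequencing in alveolar macrophages, the phagocytes that patrol the air spaces of the lung, from C57BL/6 mice. The cells were obtained by bronchoalveolar lavage 2 weeks after saline or bleomycin was instilled into the trachea, and were kept if they adhered to a culture plate. Bleomycin breaks DNA and is widely used to produce lung fibrosis in mice. There were 3 saline libraries (replicates 1, 2 and 3) and 3 bleomycin libraries (replicates 1, 2 and 5), and the question was which transcripts differ in these cells between normal and fibrotic lungs. Reads recovered from the values numbered 29899133, 27654799 and 29100186 in saline replicates 1, 2 and 3, and 35525055, 28916201 and 37147983 in bleomycin replicates 1, 2 and 5. The labels do not say that the libraries came from separate mice, so p-values measure the spread between these samples, part of which may be technical. Values below are normalized read counts given as mean ± SD over the 3 libraries of a group. Log2 fold changes, given ± SE, compare bleomycin with saline on the log2(value + 1) scale, and coordinates are on GRCm38.

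Bleomycin libraries differed widely from saline libraries. Of 13512 genes tested, 1319 rose and 527 fell after bleomycin by limma at an adjusted p under 0.05. Rises were larger than falls: 1009 genes rose at least 2-fold against 176 that fell at least 2-fold, and 474 rose at least 8-fold against 1, Fabp1, that fell as much. Of the genes that rose, 50.6% had a saline mean under 50. The groups did not overlap in 1845 of the 1846 called genes, and in 30.8% of all tested genes, where chance gives 10%. With quantile normalization 1114 genes rose and 752 fell, so that 59.7% of calls were rises, against 71.5% with the values as deposited. The total fell to 688 without bleomycin replicate 2 (522 higher, 166 lower) and to 664 without bleomycin replicate 5 (502 higher, 162 lower), and the falls to 350, 327 and 320 without saline replicates 1, 2 and 3. Without a bleomycin library 1510 of the 1846 called genes could be tested, because the filter needs 3 libraries.

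The largest changes are taken from called genes with a mean of at least 100 in the higher group, no overlap between groups and no predicted gene or clone. The 3 chains of complement C1q, which opens the classical complement pathway, were among the 8 largest rises. C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187) went from 92.6 ± 55.2 to 17837 ± 6173, a 213-fold rise (log2 7.73 ± 0.49, limma adjusted p = 6.5e-05), C1qc rose 135-fold and C1qa 124-fold. Padi2, a peptidylarginine deiminase, rose 145-fold from 2.34 ± 2.46 to 391 ± 105, and the amino acid transporter Slc36a2 120.1-fold from 13.5 ± 11.7 to 1277 ± 272. Npy, which encodes neuropeptide Y, and Nnmt, nicotinamide N-methyltransferase, had 0 reads in every saline library and were at least 158-fold and 135-fold higher, against a floor of 3 reads over the group. Mgp, matrix Gla protein, had 2 reads over the saline group and 726 over the bleomycin group, a ratio of 329 with a 95% counting interval of 90.7 to 2720. The largest fall was in the fatty acid binding protein Fabp1 (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023), from 7804 ± 3378 to 977 ± 566, 8.3-fold lower (log2 -3.05 ± 0.41, adjusted p = 0.00186). The next 7 falls were in Spag11b, 6.29-fold, the keratin Krt79, 6.06-fold, Cpne5, 5.58-fold, Lad1, 5.08-fold, Adtrp, 4.73-fold, the receptor Cd300e, 4.56-fold, and Afp, alpha-fetoprotein, 4.53-fold. The Lad1 fall did not pass without saline replicate 3 or any 1 of bleomycin replicates 1, 2 and 5 (adjusted p = 0.0522 to 0.134). Padi2, Npy, Nnmt and Mgp could not be tested without a bleomycin library, and Spag11b shares exons with a predicted gene.

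**Figure D1:**
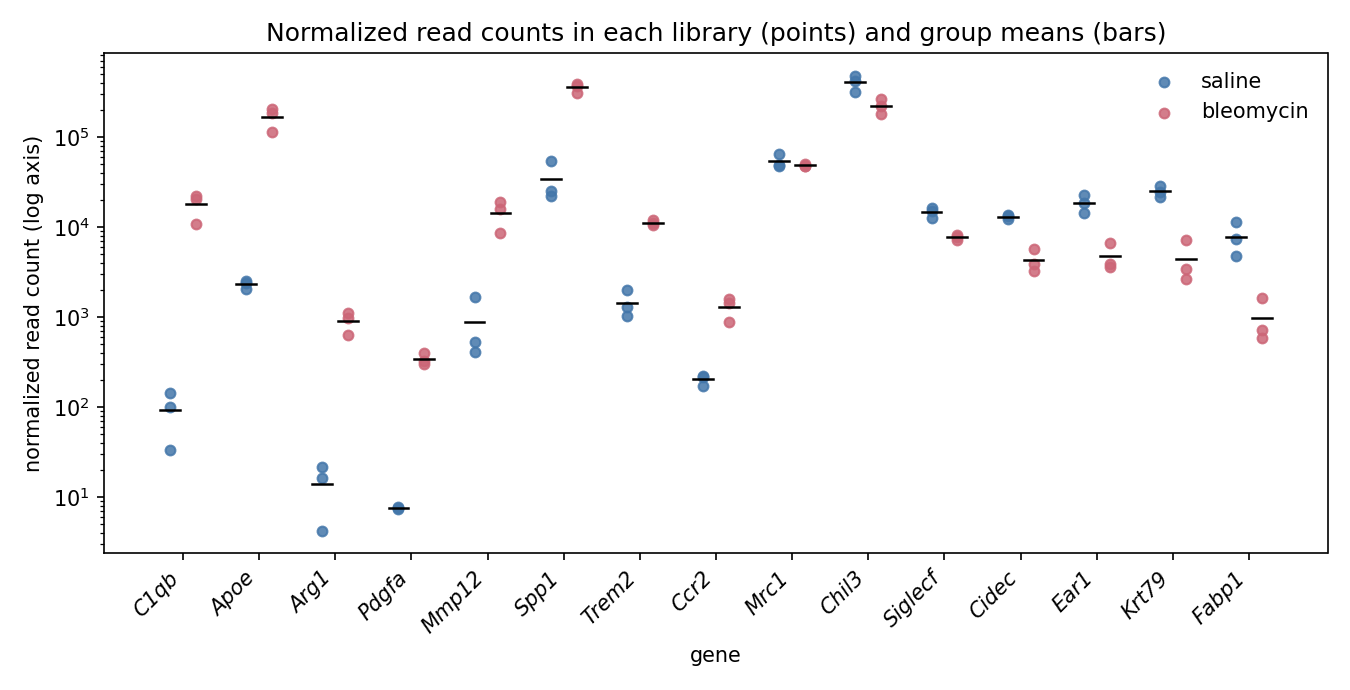
Normalized read counts (log axis) of 15 genes in the 3 saline and 3 bleomycin libraries, 1 point per library, with the group mean as a bar. C1qb to Ccr2 were higher in every bleomycin library than in any saline library, Chil3 to Fabp1 were lower, and Mrc1 did not pass the test.

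Many markers of resident alveolar macrophages fell, and most markers of monocytes and monocyte-derived macrophages rose. Of 22 resident markers tested, 12 fell and 0 rose (14 and 0 adjusted over the list alone). Siglecf (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531), a sialic acid receptor typical of these cells, went from 14580.1 ± 1790 to 7713 ± 477, 1.88-fold lower (log2 -0.91 ± 0.12, adjusted p = 0.00194). Krt79 fell from 24737 ± 3593 to 4450.5 ± 2442, Ear1, an eosinophil-associated ribonuclease, from 18485 ± 4315 to 4721 ± 1695, and the lipid droplet protein Cidec from 13025 ± 811 to 4261 ± 1267. Of 21 monocyte-derived markers tested, 16 rose and 0 fell (18 and 0 adjusted over the list alone). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), a lipid carrier, went from 2319 ± 224 to 166533 ± 48129.9, 69.8-fold higher (log2 6.12 ± 0.21, adjusted p = 4.9e-06). F13a1, a coagulation factor subunit, rose 71.7-fold, Tmem176b 26.5-fold and the monocyte chemokine receptor Ccr2 6.23-fold, from 203 ± 27.4 to 1305 ± 382. By limma's camera the resident list was lower than other genes (adjusted p = 6.7e-08) and the monocyte list higher (adjusted p = 1.1e-18), with adjusted p = 0.169 and 0.0994 with an estimated correlation. The resident count was 6 without saline replicate 3, bleomycin replicate 2 or bleomycin replicate 5, and 7 with no intensity trend or with the replicate number as a block. In the same libraries the summed T cell markers were 106.9, 81.5 and 129.4 in saline and 499.4, 1054 and 1210 in bleomycin. Ear1 shares exons with a pseudogene, and reads of near-identical family members may be split, so its level is uncertain; Tmem176b overlaps Tmem176a.

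Genes reported in macrophages of fibrotic lung rose nearly throughout: 18 of 21 rose and 0 fell (18 and 1 adjusted over the list alone). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin, went from 33721 ± 17259.9 to 353202 ± 42294, 11.3-fold higher (adjusted p = 0.000275). The platelet-derived growth factor chain Pdgfa rose 39.4-fold from 7.62 ± 0.211 to 341 ± 53.5, the lipid receptor Trem2 8.04-fold from 1439 ± 492 to 11165 ± 751, and the metalloproteinase inhibitor Timp2 4.27-fold. Of 17 genes of matrix proteases, their inhibitors and the plasminogen system, 11 rose and 0 fell (13 and 1 adjusted over the list alone). Among them were Adam8, 22-fold, and Timp1, 6.33-fold. Both lists were higher than other genes by camera (adjusted p = 8.8e-16 and 2.6e-08), also with an estimated correlation (adjusted p = 0.0474 and 0.0493). The lists share Mmp12, Mmp14, Ctsk and Timp2, so their results are not independent. Summed fibroblast markers were 306.9, 412.9 and 705.2 in saline and 1148, 556 and 1102 in bleomycin libraries. By DESeq2 1 gene of each list fell. The fibrosis count was 16, 16 and 15 without saline replicates 1, 2 and 3, and the matrix count 9, 10 and 10. They were 15 and 9 with no intensity trend, and 16 and 11 with the replicate block. Mmp14 was lost without saline replicate 1 or 3 or bleomycin replicate 2 or 5 (adjusted p = 0.0586 to 0.0864). Ctsk was lost without any library but bleomycin replicate 1 (0.0533 to 0.079). Pdgfa could not be tested without a bleomycin library, and Spp1, Pdgfa and Adam8 share exons with other annotated genes.

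Genes linked to alternative activation moved unevenly. Of 14 tested, 6 rose and 1 fell (7 and 2 adjusted over the list alone). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), arginase 1, went from 14 ± 8.88 to 902 ± 248, 69.1-fold higher (log2 6.11 ± 0.51, adjusted p = 0.000246), the elastase Mmp12 rose 19.1-fold and the lectin Mgl2 9.19-fold. Chil3, a chitinase-like protein and among the most abundant transcripts, fell from 402547 ± 83968 to 221981 ± 42535 (log2 -0.85 ± 0.23, adjusted p = 0.0388). The mannose receptor Mrc1 did not pass (log2 -0.14 ± 0.15, adjusted p = 0.644), with 53366 ± 9403 in saline and 48088 ± 1065 in bleomycin libraries. Retnla was below the test filter, with values of 31.4, 1.09 and 0 in saline and 7.19, 6.59 and 12.1 in bleomycin libraries. The list was higher by camera (adjusted p = 0.0255), with adjusted p = 0.223 with an estimated correlation and 0.0506 without an intensity trend (adjusted p = 0.000778 to 0.0506 over the settings run at the preset correlation). The Chil3 fall did not pass without saline replicate 1 or 3 or bleomycin replicate 2 or 5 (adjusted p = 0.105 to 0.204), and Chil3 has a close relative, Chil4. Of the list 0 fell with no filter or with the replicate block, and 2 at a pseudocount of 0.5, with TMM rescaling, with quantile normalization or by DESeq2. Of its 18 listed genes 7 are also in other lists, so its result is not independent of theirs. Arg1 and Mmp12 are in the fibrosis list, Ccl22 is a chemokine and a dendritic cell marker, and Chil3 is a resident marker.

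The glucose transporter Slc2a1 and hexokinase 2 rose, while 12 members of the glycolysis list did not pass the test. Of 21 genes, 8 rose and 1 fell (10 and 2 adjusted over the list alone). Slc2a1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983) went from 1352 ± 279.8 to 2403 ± 212 (log2 0.84 ± 0.16, adjusted p = 0.00873) and Hk2, which encodes hexokinase 2, from 1616 ± 469 to 2870 ± 276 (log2 0.86 ± 0.20, adjusted p = 0.0212). The muscle phosphofructokinase Pfkm rose 2.57-fold from a low level and Pgam1, phosphoglycerate mutase, 1.65-fold. The member that fell was the platelet phosphofructokinase Pfkp, from 9128 ± 706 to 6619 ± 196 (log2 -0.46 ± 0.10). Lactate dehydrogenase A, Ldha, had log2 0.14 ± 0.14 (adjusted p = 0.61), and Pfkfb3, which makes the phosphofructokinase activator fructose 2,6-bisphosphate, log2 0.44 ± 0.31 (adjusted p = 0.448). The list was higher by camera (adjusted p = 0.0233), with adjusted p = 0.169 with an estimated correlation, 0.0645 by edgeR, 0.0734 by DESeq2 and 0.0715 without saline replicate 1 (adjusted p = 0.00308 to 0.0734 over the settings run at the preset correlation). The count of rises was 4, 5, 1 and 0 without saline replicate 1, saline replicate 3, bleomycin replicate 2 and bleomycin replicate 5, 4 with no intensity trend and 2 with the replicate block, and in both of these settings 0 fell. Hk2 (adjusted p = 0.0619 to 0.0992) and Pfkp (0.0555 to 0.134) did not pass without any 1 of these 4 libraries, Pfkm (0.0638 to 0.0658) and Pgam1 (0.0678 to 0.0716) without bleomycin replicate 2 or 5, and Slc2a1 (0.0561) without bleomycin replicate 5. Slc2a1 and Pfkm share exons with other annotated genes.

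**Figure D2:**
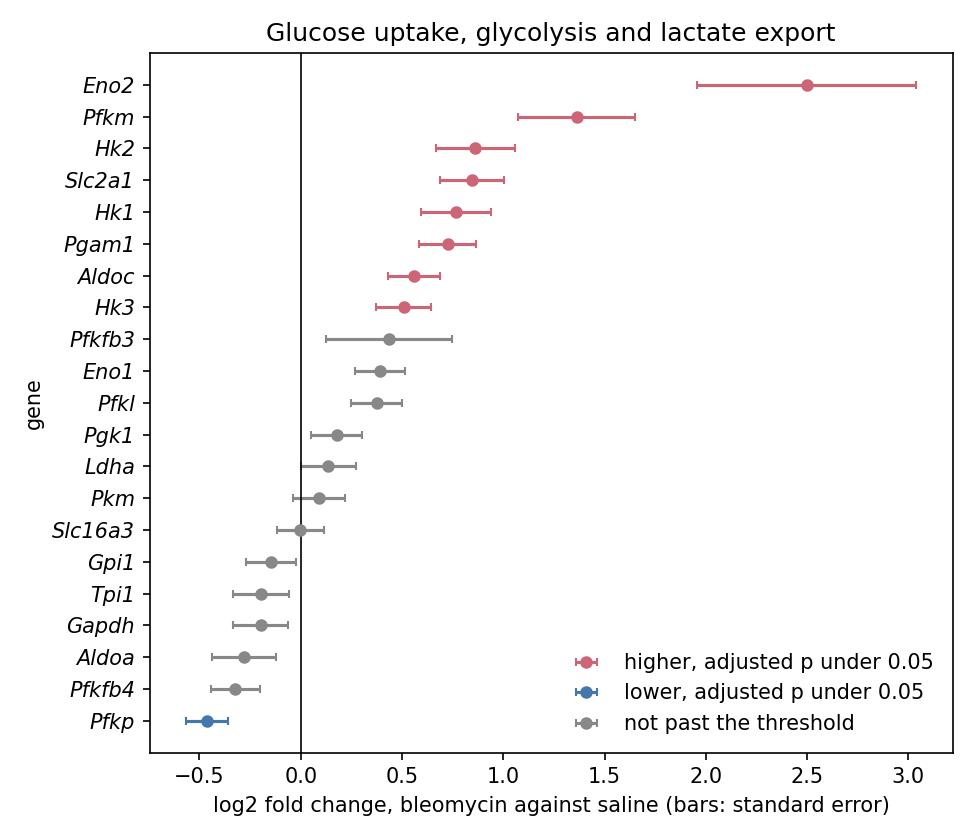
Log2 fold change of bleomycin against saline (points) with its standard error (bars) for 21 genes of glucose uptake, glycolysis and lactate export. Of these, 8 lie above 0 and 1 below 0 past the test threshold, and 12 did not pass.

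Mitochondrial pathways showed no member past the threshold in the 6 libraries. This held for 20 genes of pyruvate dehydrogenase and the tricarboxylic acid cycle, 62 nuclear genes of the respiratory chain and ATP synthase, and 19 of mitochondrial fatty acid oxidation, with 0 past limma's threshold in each list, also adjusted over the list alone. At an unadjusted p under 0.05 there were 4, 3 and 6 in that order, edgeR called 0 in each, and DESeq2 0, 1 and 1. Citrate synthase, Cs, had 7363 ± 426 in saline and 6179.9 ± 154 in bleomycin libraries (log2 -0.25 ± 0.10, adjusted p = 0.152), the ATP synthase subunit Atp5b log2 -0.31 ± 0.12 (adjusted p = 0.153) and the acyl-CoA synthetase Acsl1 log2 -0.38 ± 0.13 (adjusted p = 0.11). As groups, the cycle (median log2 -0.15, adjusted p = 0.0247) and fatty acid oxidation (median log2 -0.24, adjusted p = 0.0177) were lower than other genes by camera, with adjusted p = 0.362 and 0.381 with an estimated correlation, and neither was called by fry (adjusted p = 0.151 and 0.148). The respiratory chain was not called (median log2 -0.01, adjusted p = 0.347, or 0.879 with an estimated correlation and 0.928 by fry). Without saline replicate 3, bleomycin replicate 2 or bleomycin replicate 5 the cycle (adjusted p = 0.078, 0.116 and 0.12) and fatty acid oxidation (0.0667, 0.0678 and 0.108) did not pass, nor did they by edgeR, by DESeq2 or with quantile normalization (adjusted p = 0.00551 to 0.308 and adjusted p = 0.00124 to 0.278 over the settings run at the preset correlation). Without bleomycin replicate 1 Hadhb of fatty acid oxidation fell (adjusted p = 0.0481), as did Ndufv1 (0.0256) and Uqcrfs1 (0.0434) of the respiratory chain. Without saline replicate 2 and bleomycin replicate 1 together, chosen after the data were seen, 1 respiratory chain and 2 fatty acid oxidation genes fell and the respiratory chain list passed as lower (adjusted p = 0.000452), and with a length correction, also chosen then, 2 respiratory chain genes fell. The respiratory chain passed as lower without saline replicate 1 (adjusted p = 0.00823) or bleomycin replicate 1 (adjusted p = 0.000145), with adjusted p = 0.000145 to 0.882 over the settings run at the preset correlation.

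Some genes of cholesterol synthesis, lipid handling and the lysosome rose. Of 21 genes of cholesterol synthesis and the LDL receptor, 7 rose and 0 fell (10 and 0 adjusted over the list alone), among them Cyp51, 1.6-fold, and Msmo1, 1.65-fold. Of 22 genes of lipid uptake, storage and export, 8 rose and 0 fell (11 and 2 adjusted over the list alone). The scavenger receptor Msr1 (ENSMUSG00000025044, chromosome 8, 39581685 to 39642673) went from 934 ± 205 to 6629 ± 1320.4 (log2 2.83 ± 0.20, adjusted p = 0.000119) and the desaturase Scd1 from 1238 ± 125 to 2851 ± 381. Of 26 lysosomal genes, 13 rose and 0 fell (15 and 1 adjusted over the list alone), with cathepsin L, Ctsl, 2.79-fold and cathepsin B, Ctsb, 2.56-fold higher. All 3 lists were higher by camera (adjusted p = 2.3e-06, 0.000738 and 4.7e-08 in that order), with adjusted p = 0.169, 0.0994 and 0.114 with an estimated correlation. Without bleomycin replicate 2 the counts were 2, 6 and 8, without bleomycin replicate 5 they were 2, 5 and 8, and without saline replicate 1 or with no intensity trend the cholesterol count was 3. With the replicate block the counts were 2, 5 and 8, and without saline replicate 2 and bleomycin replicate 1 together the cholesterol count was 13. By DESeq2 1 lipid handling and 1 lysosomal gene fell. Without bleomycin replicate 1 the lysosomal regulator Tfeb fell (adjusted p = 0.0416). Cyp51 and Ctsb share exons with other annotated genes. The lipid handling and lysosomal lists have 9 and 6 members in other lists and some in common, so their results are not independent. Apoe of lipid handling is also a monocyte marker, and Ctsl and Ctsb are also in the fibrosis list.

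Some interferon-stimulated and major histocompatibility complex class II genes rose. Of 29 interferon-stimulated genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone). Oasl2 (ENSMUSG00000029561, chromosome 5, 114896936 to 114912234) went from 96 ± 36.8 to 1006 ± 467 (log2 3.32 ± 0.44, adjusted p = 0.0017) and Rtp4 rose 4.67-fold. Ifi44 had 2 reads over the saline group, and its ratio was 48.5 (95% counting interval 13.1 to 405). Of 11 class II genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone). H2-Eb1 rose from 5675 ± 1155 to 17408 ± 2805, H2-Ob 14-fold and the protease Ctss, which trims the invariant chain, 2.36-fold, and H2-Aa and H2-Ab1 also rose while H2-DMa fell. Both lists were higher by limma's camera (adjusted p = 1.1e-09 and 0.000408), with adjusted p = 0.225 and 0.216 with an estimated correlation. The interferon count was 8 without bleomycin replicate 2 or 5, and 3 class II genes rose with the replicate block. The H2-DMa fall was lost without saline replicate 1, 2 or 3 or bleomycin replicate 2 or 5 (adjusted p = 0.0688 to 0.242), and the H2-Ab1 rise without bleomycin replicate 5 (0.0643). Summed dendritic cell markers were 6557, 5050 and 6583 in saline and 6577, 8893 and 9002 in bleomycin libraries, and summed B cell markers 48.1, 36.9 and 49.8 against 164.4, 1682 and 1179. Ifi44 could not be tested without a bleomycin library.

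Inflammatory mediators and chemokines were mixed. Of 20 inflammatory mediators 3 rose, which were Ptgs2 (prostaglandin synthase 2, from 135 ± 128 to 1839 ± 1119.9, 15.5-fold, adjusted p = 0.0115), the interleukin 12 subunit Il12b (11.5-fold) and Cd40 (6.5-fold), and 2 fell, which were Il18 and Ptges (5 and 2 adjusted over the list alone). Nos2, nitric oxide synthase 2, was below the test filter, with 0 in every saline library and 5.39, 0 and 7.76 in bleomycin libraries. Of 18 chemokines, 3 rose and 0 fell, also adjusted over the list alone: Cxcl16, 5.78-fold, Ccl5, 5.4-fold, and Ccl22, 1.42-fold. Both lists were higher by camera (adjusted p = 0.04 and 0.0225), with adjusted p = 0.542 and 0.428 with an estimated correlation, and neither was called by fry (adjusted p = 0.275 and 0.145). Without saline replicate 1 neither passed (adjusted p = 0.78 and 0.742), and neither did by edgeR or DESeq2 (adjusted p = 3.7e-05 to 0.78 and adjusted p = 0.000474 to 0.742 over the settings run at the preset correlation). The inflammatory list was also not called by camera with no intensity trend (adjusted p = 0.0659) or with the length correction. The inflammatory counts were 3 higher and 4 lower without saline replicate 1, 6 and 1 without saline replicate 2, 3 and 1 without saline replicate 3, and 2 and 0 without bleomycin replicate 2 or 5. With the replicate block they were 10 and 2, and without saline replicate 2 and bleomycin replicate 1 together, chosen after the data were seen, 8 and 2. Chemokine counts were 6 higher and 1 lower with the replicate block, and 3 and 1 by edgeR or DESeq2. They were 2 higher and 2 lower (Ccl2 and Cxcl3) without saline replicate 1, 4 and 0 without saline replicate 2 or without it and bleomycin replicate 1 together, 2 and 0 without bleomycin replicate 1, and 1 and 0 without bleomycin replicate 2 or 5. Ccl22 was lost without any library but saline replicate 3 (adjusted p = 0.0626 to 0.203), and Il18 without saline replicate 2 or 3 or bleomycin replicate 2 or 5 (0.0812 to 0.134). Ptgs2, Ptges and Ccl5 were lost without bleomycin replicate 2 or 5 (highest adjusted p = 0.0536, 0.0875 and 0.0533). Cxcl16 shares exons with Zmynd15.

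Of the 6 subunits of the replicative helicase 4 fell, and some targets of p53, which responds to DNA damage, rose. Of 32 genes of DNA replication and mitosis 6 fell and 0 rose (7 and 0 adjusted over the list alone), and 26 did not pass. The helicase subunit Mcm5 went from 1583 ± 297 to 843 ± 26 (log2 -0.89 ± 0.15, adjusted p = 0.00589), 1.85-fold lower, and its partners Mcm7 and Mcm2 were 1.65-fold and 1.63-fold lower. The subunits Mcm3 (log2 -0.38, adjusted p = 0.136) and Mcm4 (log2 -0.26, adjusted p = 0.286) did not pass, nor did they with TMM rescaling, with quantile normalization or without any 1 library. Mcm6, Top2a and Tpx2 also fell, but Top2a (adjusted p = 0.0624 to 0.197) and Tpx2 (0.0696 to 0.2) did not pass without any 1 of the 6 libraries, nor Mcm6 (0.0993 to 0.167) without saline replicate 2 or 3 or bleomycin replicate 2 or 5. Of 19 p53 targets, 6 rose and 0 fell (7 and 0 adjusted over the list alone), among them Trp53inp1 (2.7-fold), Sesn1 (2.32-fold) and Zmat3 (1.85-fold). By camera the cell cycle list was lower (adjusted p = 2.6e-07), also with an estimated correlation (adjusted p = 0.0493). The p53 list was higher (adjusted p = 0.000163), with adjusted p = 0.114 with an estimated correlation. The cell cycle count was 1 with the replicate block, and 3 without saline replicate 2, saline replicate 3 or bleomycin replicate 2, and 2 without bleomycin replicate 5, where the p53 count was 3 and Mcm2 was lost (adjusted p = 0.0586). The p53 count was 10 without saline replicate 2 and bleomycin replicate 1 together. Mcm7 shares exons with Cops6 and Ap4m1.

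Some hypoxia-inducible genes rose, and the antioxidant genes Hmox1 and Cat fell. Of 15 hypoxia-inducible genes outside glycolysis 5 rose and 0 fell (6 and 0 adjusted over the list alone). The angiogenic factor Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369) went from 33 ± 17.8 to 468 ± 255 (log2 3.72 ± 0.54, adjusted p = 0.00283), Ndrg1 rose 6.64-fold and Hilpda 2.2-fold, and P4ha2 and Ddit4 also rose. Of 18 antioxidant and pentose phosphate genes, 2 fell and 0 rose (3 and 0 adjusted over the list alone). Heme oxygenase 1, Hmox1, went from 34971 ± 12008 to 13885 ± 1093 (log2 -1.27 ± 0.24, adjusted p = 0.01), and catalase, Cat, was 1.44-fold lower. By camera the hypoxia list was higher and the antioxidant list lower (adjusted p = 0.00197 and 0.00197), with adjusted p = 0.169 and 0.324 with an estimated correlation. By fry the antioxidant list was not called (adjusted p = 0.121). The hypoxia count was 3 without bleomycin replicate 2 or 5 or at a minimum of 50. The antioxidant count was 4 by DESeq2, 1 with no intensity trend, the replicate block or without saline replicate 2, saline replicate 3 or bleomycin replicate 2 and 0 without bleomycin replicate 5. Hmox1 was lost without bleomycin replicate 5 (adjusted p = 0.0518), Cat without saline replicate 2 or 3 or bleomycin replicate 2 or 5 (0.0609 to 0.0832) and Ddit4 without bleomycin replicate 2 or 5 (0.107 to 0.118). P4ha2 was lost without saline replicate 1 or 2 (adjusted p = 0.0647 to 0.077) and could not be tested without a bleomycin library.

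Markers of lymphocytes, which are not macrophages but occur in lavage fluid, rose from saline means below 100 in all members tested. All 15 tested T cell markers, all 4 B cell markers and all 3 natural killer cell markers rose, also adjusted over the list alone. Markers near 0 in saline pass the filter only by their values in the bleomycin libraries. With no filter 17 of 17 T cell, 9 of 15 B cell and 3 of 10 natural killer cell markers rose, and with a minimum of 50 in 3 libraries 2 of 2 T cell and 2 of 2 B cell markers, with no natural killer cell marker left to test. Of the 15 T cell markers 13 rose with no intensity trend, and 14 with quantile normalization, with the replicate block or without any 1 of the 3 saline libraries. Cd8b1, a chain of the CD8 coreceptor, had 0 reads in saline and was at least 30.8-fold higher, and Cd6 had a ratio of 68.8 (95% counting interval 18.7 to 574). Among B cell markers the immunoglobulin light chain Igkc was at least 156-fold higher than 0 reads in saline, Cd79a rose 30.2-fold, and Ighm and Fcrla also rose. Of natural killer cell markers Nkg7 was at least 19.6-fold higher than 0 reads in saline, Il2rb rose 24-fold, and Klrd1 also rose. By camera the lists were higher (adjusted p = 8.8e-12, 0.00026 and 0.000839 in that order), with adjusted p = 0.114, 0.169 and 0.169 with an estimated correlation. Without a bleomycin library only 3 T cell, 2 B cell and 1 natural killer cell markers could be tested, and the smaller lists could not be set-tested. Of these 3, 2 and 1 rose without bleomycin replicate 1, 1, 1 and 1 without bleomycin replicate 2, and 1, 1 and 0 without bleomycin replicate 5. Fcrla was lost without bleomycin replicate 2 or 5 (adjusted p = 0.0579 to 0.0583) and Klrd1 without bleomycin replicate 5 (0.0652).

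Markers of other cells moved unevenly. Of 12 dendritic cell markers 8 rose and 0 fell (9 and 0 adjusted over the list alone), with the cytokine receptor Flt3 from 15.5 ± 7.86 to 258 ± 101 (16-fold, adjusted p = 0.000919) and Itgae 9.43-fold higher. Of 15 lung epithelial markers 9 rose and 1 fell (10 and 2 adjusted over the list alone). Surfactant protein D, Sftpd, rose 18.9-fold and keratin 18, Krt18, 16.6-fold, while Epcam fell from 4378 ± 452 to 1426 ± 467. The summed epithelial markers were lower in each bleomycin library (5426, 5505 and 5912) than in any saline library (7175, 6941 and 6024), against the direction of most members. The mean fall of Epcam was larger than that of the sum, so the other members together did not fall. The surfactant genes Sftpa1, Sftpb, Sftpc and Sftpd summed to 75.5, 58.7 and 75.3 in saline and 376.4, 676.8 and 1019 in bleomycin libraries. Summed neutrophil markers were 2584, 4326 and 3161 in saline and 5766, 6699 and 5908 in bleomycin libraries. Of 8 neutrophil markers Cxcr2 (3.85-fold), Mmp8 (2.44-fold) and S100a8 (3.67-fold) rose and 0 fell, also adjusted over the list alone. Of 9 fibroblast markers the proteoglycan Dcn (23.6-fold), Col5a1, with 2 saline reads and a ratio of 37.6 (95% counting interval 10.1 to 316), and Col3a1 rose and 0 fell (6 and 0 adjusted over the list alone). In these lists 4, 3, 6 and 2 members in that order had a saline mean of 100 or more. Of the 6 neutrophil markers, S100a9 and Lcn2 reached it only through saline replicate 2. Neither endothelial marker tested passed by limma or edgeR (Pecam1, adjusted p = 0.0835, and Vwf, 0.0675), nor did the red blood cell marker Hbb-bs (0.228), while all 3 passed by DESeq2 and both endothelial markers passed adjusted over the list alone. No marker of eosinophils and mast cells passed the filter. By camera the dendritic (adjusted p = 1.7e-05), epithelial (1.7e-05), neutrophil (0.0429) and fibroblast (0.00537) lists were higher, with adjusted p = 0.169, 0.169, 0.306 and 0.193 with an estimated correlation. By fry the neutrophil list was not called (adjusted p = 0.0541). The dendritic count was 5 without any 1 bleomycin library, and epithelial markers had 2 falls without saline replicate 1, with quantile normalization or by DESeq2. The fibroblast list was not called without bleomycin replicate 1 (adjusted p = 0.12, 0 genes) or 5 (0.144, 0 genes), and had 1 gene called without bleomycin replicate 2 and 5 without saline replicate 3 or with the replicate block, and 0 at a minimum of 50 or without saline replicate 2 and bleomycin replicate 1 together (list adjusted p = 6.0e-06 to 0.203 over the settings run at the preset correlation). In the last 2 settings, and by DESeq2 (0.0695), camera did not call the fibroblast list either. The neutrophil list was not called without saline replicate 1 (adjusted p = 0.304) or 3 (0.0912), and had 5 genes called without saline replicate 2, where S100a9 (adjusted p = 0.0286) and Lcn2 (0.00937) also rose (list adjusted p = 0.000222 to 0.304 over the settings run at the preset correlation). Camera also did not call the neutrophil list at a pseudocount of 5 (0.0585), with no intensity trend (0.0709), by DESeq2 (0.0937) or with the replicate block (0.0771). Col3a1 was lost without saline replicate 1 or 2 or any bleomycin library (adjusted p = 0.0763 to 0.151). Pecam1 passed without saline replicate 1 (0.0497) or bleomycin replicate 1 (0.0395), and Hbb-bs without bleomycin replicate 5 (0.0335). With the length correction, or without saline replicate 2 and bleomycin replicate 1 together, 1 endothelial marker passed, and Hbb-bs passed with the replicate block. Sftpd, Dcn and Col5a1 could not be tested without a bleomycin library.

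**Figure D3:**
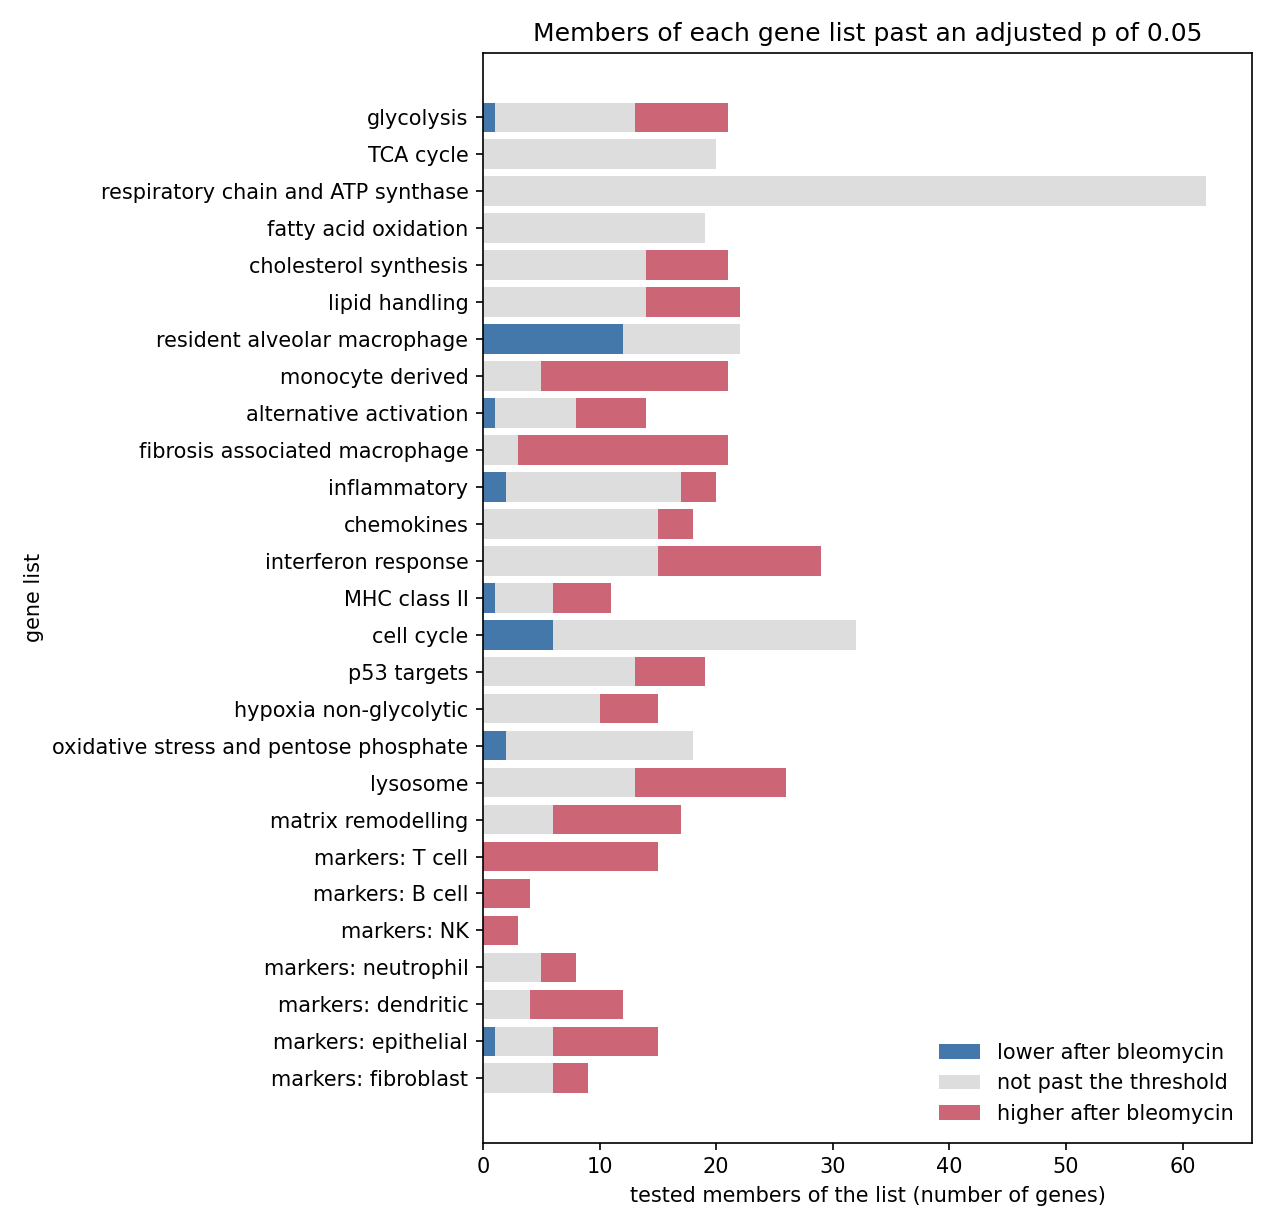
Number of tested genes in each of 27 gene lists that rose (red), fell (blue) or did not pass (grey) an adjusted p of 0.05 after bleomycin. The fibrosis list has 18 rises among 21 genes and the resident macrophage list 12 falls among 22.

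The libraries also differed in features that no gene list describes. A first principal component held 70.8% of the variance and separated the groups, with bleomycin replicate 1 nearest to saline. Correlations of log2 values across genes, which are not independent replicates, between saline libraries were 0.976 to 0.979, between bleomycin libraries 0.980 to 0.992, and across groups 0.922 to 0.954. No pair of libraries was as alike as counting noise would make it (lowest chi-square per gene 16.75). Mitochondrial transcripts made up 2.93%, 2.45% and 2.78% of saline and 1.83%, 3.42% and 3.26% of bleomycin libraries. Lysozyme 2, Lyz2, took 2.28%, 2.69% and 2.35% of saline and 4.04%, 4.84% and 4.34% of bleomycin libraries.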

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

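The setting without saline replicate 2 and bleomycin replicate 1 together and the length correction were chosen only after the result was seen. The main counts were 1846 genes, 1319 higher and 527 lower. Leaving out each library gave 664 to 1675 genes (502 to 1173 higher, 162 to 576 lower); with a bleomycin library left out, 1510 of the 1846 genes could be tested, which accounts for part of the drop, and the cause of the rest was not tested. At least a 2-fold change left 1185 genes (176 lower), and an adjusted p under 0.01 left 921 (763 higher, 158 lower), as stricter thresholds must. With the replicate number as a block 1147 genes passed, 953 higher and 194 lower. Numbers 3 and 5 each occur in 1 group only, so this fit compared just replicates 1 and 2 of each group. The deviations of same-numbered libraries correlated at -0.201 for number 1 and 0.0237 for number 2, so the numbers are not taken to pair libraries. The other settings run over all genes gave counts within 1.5 times the main ones: 1353 at a minimum of 50, 1465 with no trend, 1741 without saline 2 and bleomycin 1, 2185 with the length correction, 2313 by DESeq2 and 1813 to 2038 in the rest. Genes called both there and in the main test had the same direction in each setting.

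Of the fixed gene lists, camera called 26 of 27, and with an estimated correlation 3, which were the fibrosis, cell cycle and matrix lists. The estimated correlations ran from -0.0378 to 0.876, most of them above the preset 0.01. The lipid handling list had the lowest, yet its unadjusted camera p went from 0.00041 to 0.0177, so correlation alone does not account for the losses. Camera with an estimated correlation also judges its statistic on the few residual degrees of freedom of the 6 libraries, unlike the preset form. The losses are therefore not a measure of correlation alone, and the parts were not separated. No called list, by the direction that camera gave, and no called named gene reversed in any setting. The median log2 fold change of the neutrophil list did change sign, from 0.49 in the main test to -0.38 by edgeR and by DESeq2. It was -0.19 with the replicate block, and -0.10 and -0.18 without saline replicates 1 and 3. Lists were lost in edgeR (5), DESeq2 (7), the block (4: the tricarboxylic acid cycle, fatty acid oxidation, antioxidant and neutrophil lists), no trend (3), quantile normalization (2), and 1 each at a pseudocount of 5, at a minimum of 50 (where the T, B and natural killer cell lists had too few genes), without saline 2 and bleomycin 1, and with the length correction. Without saline replicates 1, 2 and 3 in turn 4, 0 and 3 were lost, and without bleomycin replicates 1, 2 and 5, 1, 2 and 3. The respiratory chain list was gained without saline replicate 1, without bleomycin replicate 1, and without saline 2 and bleomycin 1. Of 98 tested named genes, the block ended the call of 12, no trend 5, and no filter, a minimum of 50 and quantile normalization 2 each. Without bleomycin replicate 2 or 5, 10 and 13 lost it, and without saline 2 and bleomycin 1, 3. Depth limits the genes with few saline reads: 668 of the 1319 rises had a saline mean under 50.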

Other observations

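The tests of dilution and of neutrophils, and all genes and gene families of the opening paragraphs, were chosen only after the result was seen.

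Several transcripts outside the fixed lists changed by limma and, apart from Ldhb, kept their call without each library in turn. Ecm1, extracellular matrix protein 1, had the smallest p of the 13512 tested genes and went from 518 ± 27.4 to 10107 ± 963 (log2 4.28 ± 0.11, adjusted p = 1.3e-06). Mfge8, which bridges apoptotic cells to phagocytes, rose 26.8-fold from 502 ± 99.4 to 13496 ± 2749.8, podoplanin, Pdpn, 8.08-fold and the syndecan Sdc4 29.5-fold. Of single receptor genes, Cmklr1, the chemerin receptor, rose 89.4-fold, C3ar1, the receptor of complement fragment C3a, 42.9-fold and Slamf7 41.8-fold. Other receptors fell, among them Cd300e and Fpr2, and receptors were not tested as a group. Of prostaglandin genes Ptgs1 rose 15.2-fold and Hpgd, which degrades prostaglandins, 6.04-fold. Of those in the inflammatory list, Ptgs2 rose and Ptges fell, but both lost their call without bleomycin replicate 2 or 5. Among falls, cyclin D2, Ccnd2, went from 6656 ± 1993 to 1970.3 ± 152, its partner kinase Cdk6 was 2.13-fold lower, the peroxisomal thiolase Acaa1b 4.03-fold, galanin, Gal, 3.95-fold, the formyl peptide receptor Fpr2 2.55-fold and fractalkine, Cx3cl1, 2.52-fold. Ldhb, the lactate dehydrogenase chain not among the glycolysis genes listed, rose from 7.96 ± 1.38 to 772 ± 59.7 (86.8-fold, adjusted p = 4.9e-06) while Ldha did not pass; it could not be tested without a bleomycin library.

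Gene families were formed by the letters of the symbol, 146 with at least 10 tested members. Of 11 tetraspanins 7 rose and 0 fell, with Tspan3 5.27-fold, Tspan4 4.13-fold and Tspan13 3.76-fold higher. Of 15 genes named Ifi 10 rose and 0 fell, with Ifi27l2a 8.17-fold and Ifi209 15.4-fold. Both families were higher by camera (adjusted p = 2.1e-05 for each) and neither was called with an estimated correlation (adjusted p = 0.616 and 0.714).

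Resident macrophage markers, 5 of which are in other lists too, fell by unequal amounts, from log2 -3.05 for Fabp1 to members with values near 0 such as Lpl (-0.02) and Itgax (0.07), which did not pass. If cells lacking these transcripts had only diluted resident cells, all would fall by 1 factor. The common log2 fold change was -0.54, and 13 of 22 members had a 95% interval that excluded it, 6 above and 7 below, where chance gives 1.1, which argues against dilution alone. Length bias is argued against by a correction that left 12 of the 12 falls past the threshold. Arriving macrophages that carry some of these transcripts, and a change within resident cells after bleomycin, may both contribute, and neither was tested.

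T cell markers rose in all bleomycin libraries, and none of the 15 tested had a saline mean of 100 or more. A candidate explanation is T cells left on the plate, although the washes would remove many cells that do not adhere. Of 15 further T cell transcripts 13 were tested, with a median log2 fold change of 4.77, and 12 rose, as T cells would require. The most abundant listed marker was Lat, at 171 ± 12.3 after bleomycin, whereas Il7r reached 1679 ± 702, above the summed T cell markers of 499.4, 1054 and 1210 in bleomycin replicates 1, 2 and 5, so Il7r may have another source as well. Other explanations were not tested.

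S100a8 (from 279 ± 138 to 974 ± 271), Mmp8 and Cxcr2 rose, and neutrophils could bring all 3, although 6 of the 8 neutrophil markers had a saline mean of 100 or more. For S100a9 (4.9, 503 and 7.42 in saline replicates 1, 2 and 3) and Lcn2 (14.7, 319 and 8.48) that mean rests on replicate 2. Neutrophils carry S100a9 at levels like those of S100a8, but the highest ratio of S100a9 to S100a8 in a bleomycin library was 0.0797, which argues against neutrophils as the source of most of the S100a8. S100a9 is also more abundant in neutrophils than Mmp8 or Cxcr2, yet it was at most 0.0667 of the rise of either over its saline mean, which argues against them there too. Saline replicate 2 stood apart, with S100a9 at 503 and Lcn2 at 319, and without it S100a9 (log2 2.36, adjusted p = 0.0286) and Lcn2 (log2 2.23, adjusted p = 0.00937) passed as higher after bleomycin, as a few neutrophils would give, so a small number of them stays open. A change of S100a8, Mmp8 and Cxcr2 in the macrophages after bleomycin also stays open and untested.

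Over the 10 splits of the 6 libraries into 3 and 3, the real split gave 1846 genes and the highest of the others 0. Only 1 split gave as many genes, the real one, and 10 splits are too few for a share under 0.05. Every other split mixes saline and bleomycin libraries, so the group difference widens the spread within its sides and lowers its count. The 0 of the other splits is therefore no further support. Bleomycin replicate 1 had the smallest change of the 3 bleomycin libraries in 71% of the called genes, and its median change was 0.807 of that of the other 2. Cxcl2 was 2389.6, 29743 and 10709 and Cxcl3 384, 12998 and 2313 in saline replicates 1, 2 and 3. Without saline replicate 2 and bleomycin replicate 1, 1741 genes passed, 1176 higher and 565 lower.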
